A study of Rhodotorula toruloides with 36 samples.

How the data were processed

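The 36 samples were of Rhodotorula toruloides IFO0880, a yeast strain, in 12 groups of 3 that differ in nitrogen, acetate and time. Per the labels' protocols, 3 colonies were grown in glucose medium and each washed pellet was shared among 4 flasks. The labels do not say whether a replicate number marks a colony, or whether the 3 times came from the same flasks. With 4 combinations of nitrogen and acetate, 4 flasks per colony give 1 flask per combination and colony. The same flasks may therefore have been sampled at all 3 times. The tests treat libraries as independent, so comparisons across times may ignore such a pairing. RNA was made into stranded mRNA libraries (Watchmaker kit) and read from both ends for 151 cycles on 1 lane of a NovaSeq X Plus, per the labels' protocols.

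Each library's deposited values are counts per mRNA of the gene catalogue for assembly version 4 of the strain. The submitters' processing notes list Trimmomatic 0.39, FastQC 0.11.9, MultiQC 1.9, STAR 2.7.10a, featureCounts and Subread 2.0.4, without order, roles or settings. The strand setting and the handling of reads with several matches are not stated. The sample description speaks of a unit scaled to library size, but the deposited values are whole-number counts whose totals differ between libraries, and they were used as raw counts. The catalogue gives mRNA and protein numbers, exons and scaffold positions. The gene table at hand is of another strain, NP11, and no table at hand pairs the 2 kinds of identifier. All 25 gene lists fixed before the data were examined therefore had 0 members, and the gene set tests planned for them were not run. Checks that need a genome sequence, of GC content and of paralogs, were not made.

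Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of the annotated genes 8314 passed edgeR's filter on low counts and 176 did not. Libraries were scaled by TMM, and edgeR's quasi-likelihood F-test was fitted to all 36 libraries with 1 mean per group. The 21 comparisons were 6 of acetate with none, 6 of low with high nitrogen, 4 of 88 with 48 h, and 5 interactions, each the difference between 2 acetate effects. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with adjusted p below 0.05 were called. A 2-fold change also had an absolute log2 fold change of at least 1. The SE of a gene's log2 fold change or interaction is its absolute value divided by the square root of F. It is not a standard error of the fit, and it can be too small for genes with few counts. CPM were computed with the TMM factors, and log2 CPM with a prior count of 2. All adjusted p in the text are from this edgeR test unless another is named. The tests, comparisons, thresholds and the alternatives, apart from those named below, were chosen before the data were examined.

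Genes are named by a rule fixed at the same time. Since no names were at hand, its fallback applies: the 2 identifiers with the highest and the 2 with the lowest log2 fold change per comparison. The criteria of the rule's first part were carried into the fallback, which its wording leaves open. They are adjusted p below 0.05, a mean of at least 10 CPM in the higher group and, except for interactions, no overlap between the libraries of the groups. With 3 against 3 libraries, no overlap arises by chance in 10% of genes. Where a lower group had 1 to 3 counts, the ratio of counts is given with a 95% Poisson interval. The order among named genes was not tested.

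Several analyses were defined after the data were seen. These are the genes changed at least 2-fold by acetate at 48 h in both nitrogen media, the overlaps and correlations between comparisons, and runs of neighbouring genes. Set scores are the mean log2 CPM over members in a library, compared by exact permutation of 3 against 3 libraries. Runs were tested against 10000 shuffles of gene positions in 32 tests, with Benjamini-Hochberg adjustment. Overlaps are given beside the number expected for independent lists.

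Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no filter and a filter of at least 10 CPM in at least 3 libraries, a block for replicate number, a fit of only the groups compared, and each library left out in turn. Thinning all libraries to the smallest total was added after the data were seen. So was leaving out together the 3 libraries whose 2 replicate pairs both had a chi-square per degree of freedom over 4 times that of the third pair, and the 4 for which it was over 3 times. For each pairwise comparison all 10 splits of the 6 libraries were fitted, and for each interaction 100 splits were drawn. Outlying libraries were not tested within groups of 3.

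The tests were tried on simulated counts with 200 of 8314 genes changed, 50 at each of 4 sizes. Counts were drawn from group means and dispersions estimated from the data, with the same dispersion of a gene in all groups. The data had many more changed genes, unequal spread between groups and libraries that stood apart, which the trial does not cover. For acetate in low nitrogen at 48 h edgeR recovered 11 of 50 genes at 1.25-fold, 33 at 1.5-fold, 43 at 2-fold and 47 at 4-fold, and called 7 of 8114 unchanged genes. For the interaction of acetate with nitrogen at 48 h it recovered 3, 19, 40 and 45 of 50, and called 8 unchanged genes. Annotation and figures were made with Python 3.11.15, figures with matplotlib 3.10.9.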

Results

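Rhodotorula toruloides is a red basidiomycete yeast that stores lipid when nitrogen runs short. Messenger RNA of strain IFO0880 was sequenced from cultures that differed in nitrogen, in acetate and in time. The series title names acetate and the use of xylose, and the labels do not give the carbon source of the sampled cultures. Low nitrogen was 0.1 g/L ammonium sulfate, to which the design text adds 0.75 g/L yeast extract. No yeast extract level is given for high nitrogen, so differences named as nitrogen effects may include one in yeast extract. High nitrogen is given as 5 g/L ammonium sulfate in the treatment protocol and as 10 g/L in the design text, and the labels do not settle which. Acetate was absent or at 2 g/L, and cells were taken at 48, 64 and 88 h. The 12 combinations had 3 biological replicates each, 36 libraries in all. The total of each library lay between 10173719 and 63311529 counts over the annotated genes, of which 8314 had enough counts to be tested and 176 had not. A level of 3 counts corresponds to 0.0497 CPM, the counts scaled to TMM-adjusted library size, in the deepest library and 0.410 CPM in the shallowest, which was replicate 1 of low nitrogen with acetate at 64 h. The genes carry catalogue numbers, and nothing used here pairs these with names or functions, so genes are given by number, protein number and position in the version 4 assembly of strain IFO0880.

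Nitrogen set the libraries apart first. The first principal component of log2 CPM held 45.1% of the variance and separated all 18 low-nitrogen from all 18 high-nitrogen libraries. The second held 14.9%, fell with time within each medium, and was higher with acetate than without it at each time in both nitrogen media. Within groups, Pearson's r of log2 CPM across genes lay between 0.977 and 0.998. Every replicate pair differed by more than sampling noise, with a chi-square per degree of freedom between 8.33 and 156. In 4 groups 1 library stood apart from the other 2. In high nitrogen replicate 2 without acetate at 88 h gave 156 and 88.3, against 14.6 for the other pair, replicate 2 without acetate at 64 h 119 and 104 against 19.4, and replicate 3 with acetate at 48 h 126 and 110 against 22.9. In low nitrogen replicate 1 without acetate at 64 h gave 43.5 and 40.9 against 11.2. All were kept. The 10 most abundant genes took 10.2% ± 0.427 of the counts (SD, n = 3) in low nitrogen without acetate at 88 h and 10.3% ± 0.377 with acetate. In high nitrogen at 88 h they took 3.92% ± 0.0887 without acetate and 4.62% ± 0.0887 with it.

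**Figure D1:**
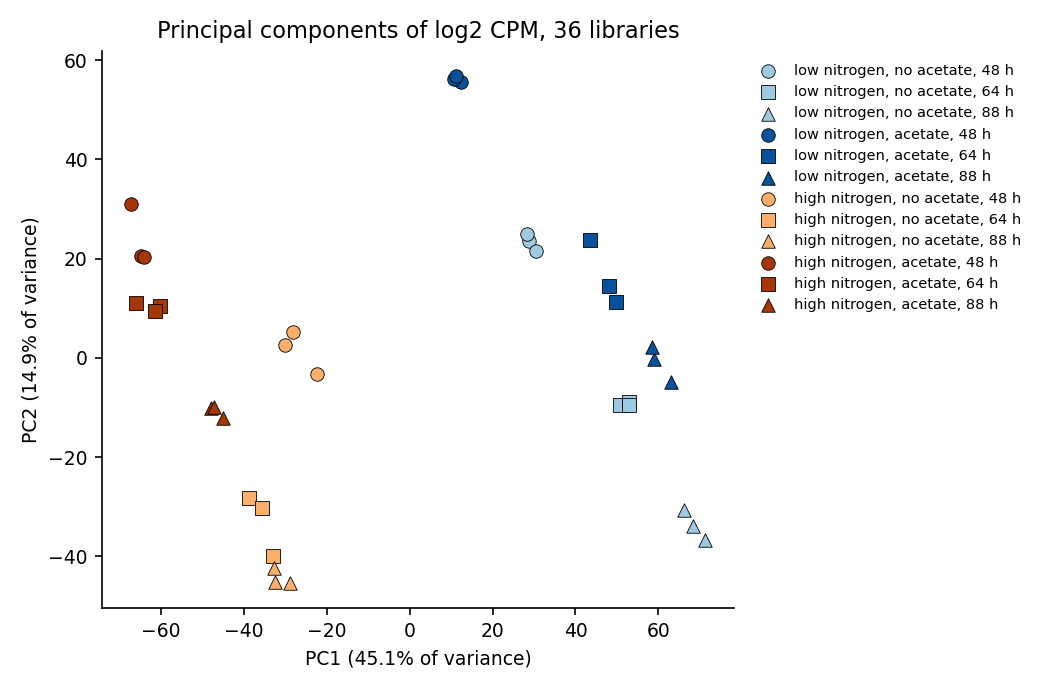
Scores of the 36 libraries on the first and second principal component of log2 CPM, with colour for nitrogen and acetate and symbol for time; each symbol is 1 library. Low-nitrogen libraries have positive and high-nitrogen libraries negative scores on the first component, which held 45.1% of the variance.

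The first question was which genes acetate changed under low nitrogen. The largest rise at all 3 times among genes meeting the naming rule was that of mRNA_5861 (protein 14229, scaffold 5, 1105736 to 1108814, minus strand, 19 exons). Its level was 27.2 ± 1.16 CPM without and 3413 ± 632 CPM with acetate at 48 h (mean ± SD, n = 3), a log2 fold change of 6.97 (SE 0.33, adjusted p = 1.14e-16). At 64 h it was 18.9 ± 1.75 against 3147 ± 624 CPM, and at 88 h 25.2 ± 1.04 against 2565 ± 97.2 CPM. The second-largest rise at 48 and 64 h was that of mRNA_6255 (protein 14623, scaffold 6, 365616 to 367386, minus strand), from 9.25 ± 0.169 to 859 ± 175 CPM and from 7.94 ± 0.272 to 578 ± 216 CPM. At 88 h it was that of mRNA_7794 (protein 16162, scaffold 8, 1082100 to 1083508), from 17.2 ± 8.30 to 491 ± 36.3 CPM (adjusted p = 3.78e-15).

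The genes lowered most by acetate in low nitrogen changed with time. At 48 h mRNA_7939 (protein 16307, scaffold 9, 58388 to 59651) stood at 10.5 ± 0.796 CPM without acetate and at 0.0912 ± 0.0116 CPM with it, the latter from 7 counts over the 3 libraries. At 64 h its levels were 11.0 ± 2.37 and 0.0695 ± 0.0606 CPM, the latter from 4 counts over the 3 libraries. Also at 48 h, mRNA_4051 (protein 12419, scaffold 2, 1242225 to 1242676) went from 43.0 ± 8.90 to 0.434 ± 0.144 CPM. By 88 h the largest fall was that of mRNA_1581 (protein 9949, scaffold 11, 651714 to 653081, coding length 318 bp), from 1025 ± 181 to 6.84 ± 1.42 CPM, a log2 fold change of -7.23 (SE 0.25, adjusted p = 5.41e-19). At 64 h the same gene had gone from 555 ± 63.6 to 6.47 ± 2.26 CPM. The next-largest fall at 88 h was that of mRNA_1169 (protein 9537, scaffold 10, 563221 to 566148), from 1111 ± 366 to 34.3 ± 5.68 CPM.

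In counts, acetate in low nitrogen changed 4249 genes at 48 h, 3481 at 64 h and 3948 at 88 h (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). At least 2-fold changes were fewer, with 326 genes higher and 549 lower at 48 h. There were 305 higher and 208 lower at 64 h, and 393 higher and 252 lower at 88 h. At 48 h 2087 genes were higher and 2162 lower, against 2669 and 1666 when libraries were scaled by their totals alone. At 64 h 1915 were higher and 1566 lower, against 1110 and 2939 with totals alone. At 88 h 2092 were higher and 1856 lower.

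Acetate under high nitrogen moved more genes and in part other ones. At 48 h mRNA_6255 rose from 4.64 ± 0.852 to 1681 ± 258 CPM (log2 fold change 8.50, SE 0.29, adjusted p = 3.62e-20) and mRNA_1084 (protein 9452, scaffold 10, 371837 to 373526) from 0.685 ± 0.169 to 121 ± 2.89 CPM. In the same comparison mRNA_1581 fell from 988 ± 89.2 to 2.09 ± 0.172 CPM (log2 fold change -8.88, SE 0.28, adjusted p = 4.57e-21), and mRNA_1816 (protein 10184, scaffold 12, 282501 to 284889) from 84.4 ± 25.9 to 0.513 ± 0.0773 CPM. At 64 h mRNA_1346 (protein 9714, scaffold 11, 50487 to 51327) rose from 0.186 ± 0.0369 to 18.2 ± 4.32 CPM and mRNA_6255 from 7.19 ± 2.41 to 491 ± 21.2 CPM. The largest falls at 64 h were those of mRNA_1684 (protein 10052, scaffold 11, 883850 to 884776), from 10.2 ± 4.88 to 0.179 ± 0.0401 CPM, and of mRNA_1581, from 834 ± 251 to 15.4 ± 4.19 CPM. At 88 h other genes led. The rises were those of mRNA_6044 (protein 14412, scaffold 5, 1510436 to 1511474), from 2.55 ± 0.970 to 83.7 ± 21.6 CPM, and of mRNA_2325 (protein 10693, scaffold 13, 613315 to 614433), from 4.44 ± 1.46 to 130 ± 6.54 CPM. The falls were those of mRNA_4664 (protein 13032, scaffold 3, 726473 to 727733), from 687 ± 422 to 7.70 ± 1.1 CPM, and of mRNA_428 (protein 8796, scaffold 1, 995646 to 996987), from 11.6 ± 6.06 to 0.424 ± 0.123 CPM. The last gene overlaps a neighbour on its own strand, so its counts are uncertain. Without acetate the single libraries had 1022, 213 and 825 CPM of mRNA_4664, the lowest of them replicate 2, which stood apart. The log2 fold change of this gene was -6.49, and -6.95 without that replicate and -6.09 without replicate 1.

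The test called 5729 genes at 48 h, 5559 at 64 h and 6287 at 88 h in high nitrogen. The 2-fold changes were 918 higher and 990 lower at 48 h, 730 higher and 784 lower at 64 h, and 1067 higher and 1189 lower at 88 h. At 48 h 2854 genes were higher and 2875 lower, against 2281 and 3504 with library totals alone. At 64 h the split was 2527 to 3032, against 1665 to 4288 with totals alone, and at 88 h it was 3226 to 3061, against 1642 to 4850. Scaling by totals alone moved the median log2 change of all genes by over 0.1 in 15 of the 21 comparisons, by between -0.54 and 0.46.

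**Figure D2:**
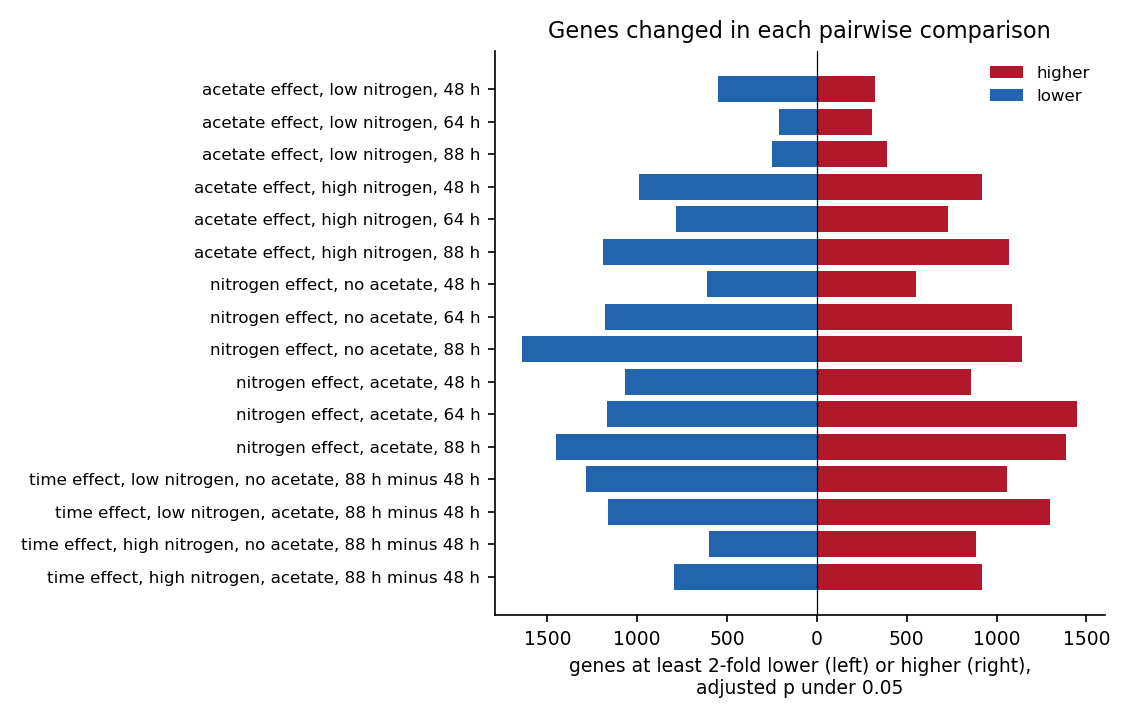
Number of genes at least 2-fold lower (left, blue) or higher (right, red) at adjusted p below 0.05 in the 16 pairwise comparisons; acetate effects are with minus without acetate and nitrogen effects low minus high. Acetate changed 326 genes upward and 549 downward in low nitrogen at 48 h, and 918 upward and 990 downward in high nitrogen.

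Acetate moved a shared group of genes at 48 h in both nitrogen media. Of the genes at least 2-fold higher, 159 were common to both media, against 36.0 for independent lists of those sizes, and of those lower 286 were common, against 65.4. These 159 raised and 286 lowered genes were picked on their values at 48 h, so only their values at 64 and 88 h played no part in the choice. Those come from other libraries, but the labels do not say whether from other flasks. Among the 159, the median log2 change in low nitrogen was 1.67 at 48 h, 1.20 at 64 h and 0.92 at 88 h. In high nitrogen it was 2.09, 1.16 and 0.29. At 88 h 102 of them were still called higher and 4 lower in low nitrogen, and 70 higher and 36 lower in high nitrogen. The mean log2 change at 88 h was 1.12 in low nitrogen. In high nitrogen it was 0.31, and -0.15 with library totals alone. The 286 lowered genes had a median log2 change of -1.57, -0.35 and -0.02 in low nitrogen at the 3 times, and of -2.16, -0.61 and 0.33 in high nitrogen. Their mean change in high nitrogen at 88 h was 0.13, and -0.34 with totals alone. It was 0.01 without replicate 1 with acetate and 0.17 without replicate 2 without acetate, so no direction is given for it.

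Averaged over members in each library, the 159 genes stood higher in all 3 acetate than in all 3 control libraries at 64 and at 88 h in both media (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). At 88 h the change of the set was 0.76 log2 units larger in low than in high nitrogen (SE 0.08, from the spread between libraries). From the fitted fold changes it was 0.81, and 1.26 with library totals alone. With acetate the libraries scored 3.98 to 4.15 in low and 4.17 to 4.21 in high nitrogen at 88 h. These had fallen from 4.94 to 5.22 and 5.78 to 6.08 at 48 h. Without acetate the scores at 88 h were 2.88 to 3.04 and 3.81 to 3.92, so the media then differed mostly without acetate. At 64 h the difference was -0.01 (SE 0.16). For the 286 lowered genes the differences were 0.07 (SE 0.14) at 64 h and -0.28 (SE 0.09) at 88 h. From the fitted fold changes the latter was -0.23, 0.23 with library totals alone and -0.11 without replicate 1 of high nitrogen with acetate, so no direction is given for it.

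**Figure D3:**
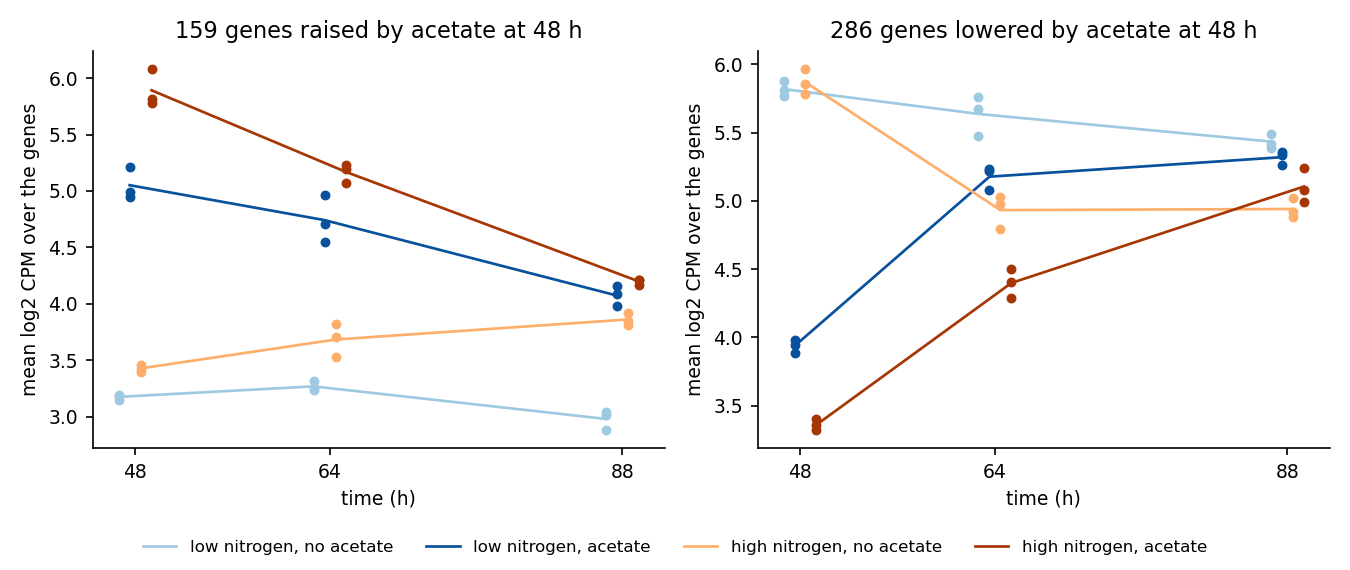
Mean log2 CPM over the 159 genes raised (left) and the 286 genes lowered (right) by acetate at 48 h in both nitrogen media, against time in hours; points are libraries and lines join group means of 3. At 48 h the groups differ by selection; at 88 h the raised genes kept a median log2 change of 0.92 in low and 0.29 in high nitrogen, with the mean in high nitrogen changing sign under scaling by library totals alone.

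Acetate effects were partly carried from 48 to 88 h. In low nitrogen 105 of the 326 genes raised at 48 h were also raised at 88 h, against 15.4 for independent lists, and 60 of the 549 lowered genes were also lowered, against 16.6. In high nitrogen 258 of 918 raised and 322 of 990 lowered genes were shared, against 118 and 142. Changes in the opposite direction at 88 h were found for 3 raised and 34 lowered genes in low nitrogen, against 9.88 and 26.0 for independent lists, and for 75 and 136 in high nitrogen, against 131 and 127. At all 3 times in both media, 19 genes were at least 2-fold higher and 6 at least 2-fold lower with acetate. Across genes, which are not independent replicates, acetate effects in low and high nitrogen correlated with Pearson's r of 0.437 at 48 h, 0.325 at 64 h and 0.299 at 88 h.

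**Figure D4:**
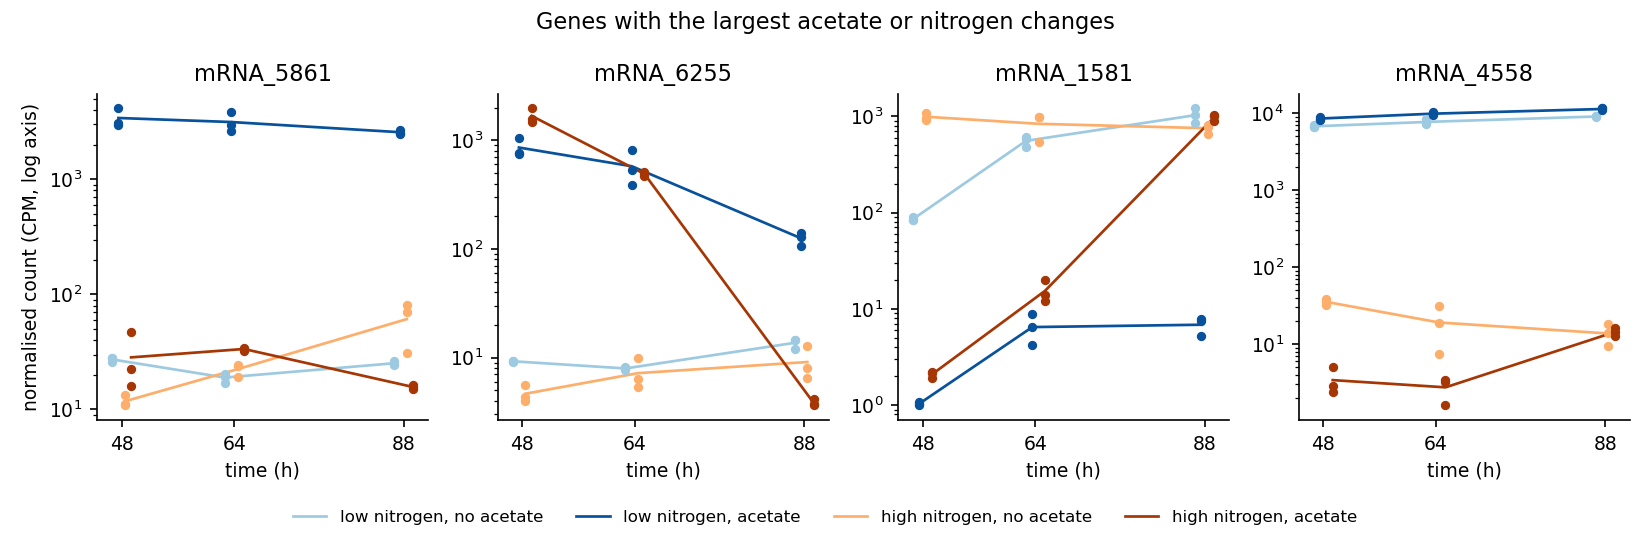
Normalised counts (CPM, log axis) of 4 genes against time in hours; points are libraries, shifted sideways by group, and lines join group means of 3. mRNA_5861 stood between 2565 and 3413 CPM in low nitrogen with acetate and at 61.0 CPM or below in the other groups, while mRNA_6255 fell to 3.82 CPM by 88 h in high nitrogen with acetate, mRNA_1581 rose there to 970 CPM, and mRNA_4558 stood between 6736 and 11316 CPM in the low-nitrogen groups.

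The second question was what nitrogen changed at a given time and acetate level, with low set against high. Low nitrogen raised mRNA_2554 (protein 10922, scaffold 14, 431704 to 432671) in all 6 comparisons. Without acetate at 88 h it stood at 532 ± 96.1 CPM in low and 0.0436 ± 0.0519 CPM in high nitrogen, the latter from 4 counts over 3 libraries (adjusted p = 1.63e-24). The fitted log2 fold change of mRNA_2554, 13.31, rests on those few counts, and its SE of 0.31, derived from F, understates their uncertainty. This log2 fold change was 14.54 without replicate 2 and 12.94 without replicate 3 of high nitrogen. At 48 h that of mRNA_2554 went from 12.66 to 13.30 without acetate and from 11.16 to 12.28 with it when replicate 1 of high nitrogen was left out. It was 12.41 without acetate when replicate 2 of high nitrogen was left out. With acetate it was 10.61 when replicate 3 of high nitrogen was left out. At 64 h with acetate it went from 11.87 to 12.47 without replicate 2 of high nitrogen and to 11.36 without replicate 1. Low nitrogen also raised mRNA_4558 (protein 12926, scaffold 3, 457914 to 459915), which stood at 11316 ± 372 CPM in low and 14.4 ± 1.64 CPM in high nitrogen with acetate at 88 h. Its log2 fold change with acetate was 11.29 at 48 h, 11.88 at 64 h and 9.62 at 88 h, and without acetate at 88 h it was 9.36. Without acetate the second-largest rises were those of mRNA_2010 (protein 10378, scaffold 12, 734428 to 736399) at 48 h, from 0.0453 ± 0.0166 to 15.7 ± 1.35 CPM, and of mRNA_8105 (protein 16473, scaffold 9, 424509 to 425542) at 64 h, from 7.60 ± 4.88 to 6475 ± 525 CPM. The log2 fold change of mRNA_8105 was 9.75, and 10.37 without replicate 2 and 9.41 without replicate 1 of high nitrogen.

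Low nitrogen lowered mRNA_4457 (protein 12825, scaffold 3, 230802 to 232972), which had 3254 ± 658 CPM in high and 2.7 ± 0.312 CPM in low nitrogen with acetate at 88 h (log2 fold change -10.22, SE 0.61, adjusted p = 3.59e-15). It was among the 2 largest falls at all 3 times with acetate and at 64 h without it. At 48 h with acetate the log2 fold change of mRNA_4457 was -9.74, and -11.18 without replicate 3 and -9.32 without replicate 2 of low nitrogen. At 48 h mRNA_668 (protein 9036, scaffold 1, 1608955 to 1610932) fell from 194 ± 126 to 0.293 ± 0.104 CPM with acetate and from 111 ± 88.0 to 0.527 ± 0.242 CPM without it. Without acetate at 48 h mRNA_7239 (protein 15607) fell from 14.6 ± 4.36 to 0.0652 ± 0.00719 CPM, the latter from 6 counts. Its fitted log2 fold change of -7.72 (SE 0.63) and that of mRNA_668, -7.68 (SE 0.64), were the 2 lowest there among genes meeting the naming rule, and their order is not distinguished. That of mRNA_668 was -6.82 without replicate 2 of high nitrogen. At 64 h mRNA_4106 (protein 12474, scaffold 2, 1370087 to 1372374) fell from 1116 ± 454 to 2.90 ± 0.122 CPM. At 88 h mRNA_1415 (protein 9783, scaffold 11, 220311 to 221980) fell from 541 ± 186 to 0.615 ± 0.135 CPM, and mRNA_7238 from 248 ± 122 to 0.378 ± 0.159 CPM.

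More genes were called at 64 and 88 h than at 48 h. Without acetate they were 4907, 6135 and 6440 at 48, 64 and 88 h, and with acetate 5838, 6315 and 6428. With acetate and library totals alone 6524 were called at 64 h and 6431 at 88 h, so no order is given for these 2 times. The 2-fold changes without acetate were 550 higher and 613 lower at 48 h, 1087 and 1178 at 64 h, and 1144 and 1638 at 88 h. With acetate they were 860 higher and 1065 lower, 1448 and 1169, and 1387 and 1453. Without acetate 2417 genes were higher and 2490 lower at 48 h, against 1649 and 3242 with library totals alone. At 64 h 2939 were higher and 3196 lower, against 1629 and 4697, and at 88 h 3126 and 3314, against 1484 and 5109. With acetate at 64 h 3242 were higher and 3073 lower, against 2198 and 4326 with totals alone. In all 6 comparisons 208 genes were at least 2-fold higher and 128 at least 2-fold lower in low nitrogen. Nitrogen effects without and with acetate correlated across genes with r of 0.553, 0.742 and 0.713 at the 3 times.

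Nitrogen also moved groups of neighbouring genes. A run was taken as at least 4 adjacent annotated genes, all at least 2-fold changed in 1 direction, a definition chosen after the data were seen. Such runs held more genes than shuffled positions gave in all 12 tests of nitrogen, and also in 7 of 12 tests of acetate and 6 of 8 of time (adjusted p below 0.05), so they are not particular to nitrogen. For acetate in high nitrogen at 48 h they held 34 higher and 54 lower genes, against means of 4.24 and 5.64 over shuffles. In 3 regions every gene lay in a run in all 6 nitrogen comparisons, and these regions too were chosen after their values were seen. Low nitrogen lowered 5 plus-strand genes, mRNA_7235 to mRNA_7239, on scaffold 7 from 1191000 to 1200363, with a median log2 change between -2.07 and -3.50 over the 6 comparisons. In this region mRNA_7238 (protein 15606) had log2 fold changes between -5.89 and -10.16. Its neighbour mRNA_7239 had between 1 and 7 counts per low-nitrogen group. The smallest gap between neighbours there is 0 bp. Low nitrogen raised 4 plus-strand genes, mRNA_593 to mRNA_596, on scaffold 1 from 1421997 to 1434239 (medians 1.39 to 2.55), and 5 plus-strand genes, mRNA_7418 to mRNA_7422, on scaffold 8 from 234238 to 241176 (medians 1.33 to 2.06).

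**Figure D5:**
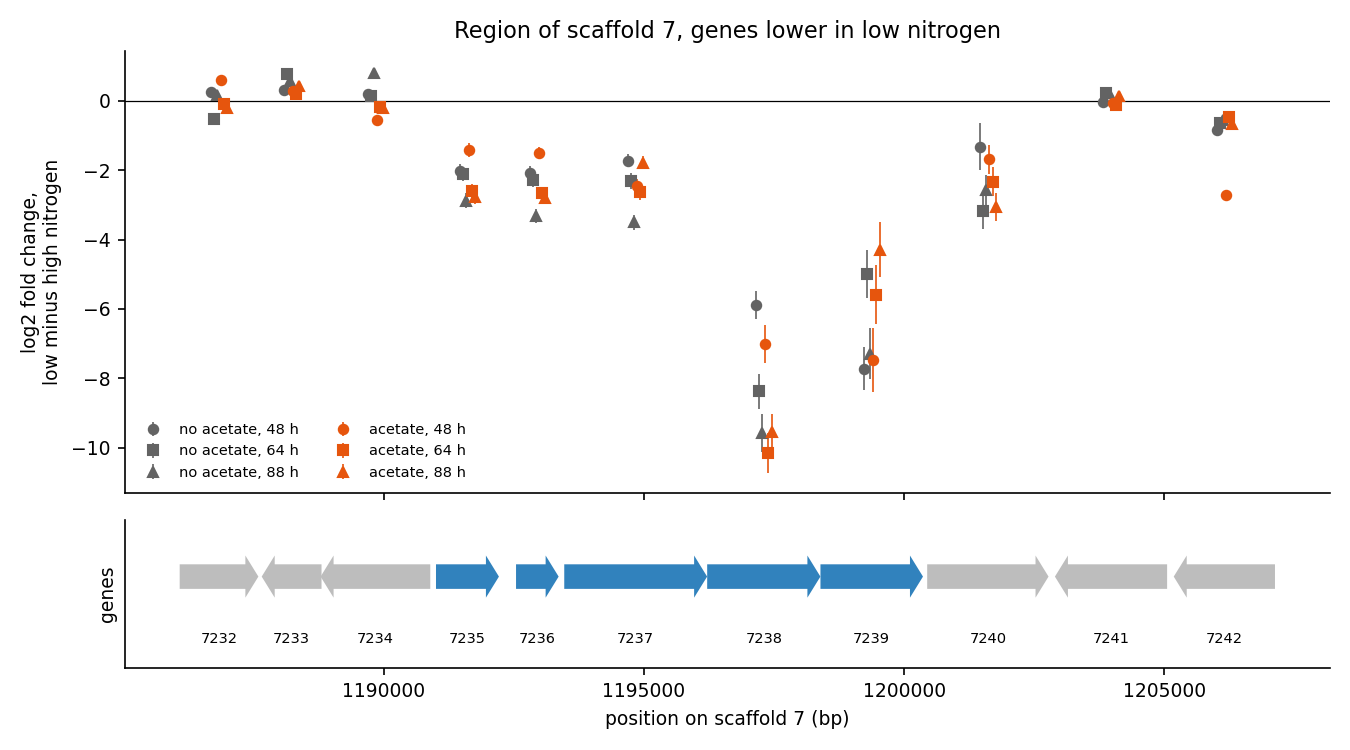
Log2 fold changes (low minus high nitrogen, bars are SE derived from F) of 11 neighbouring genes on scaffold 7 above their positions in bp, with blue arrows for the 5 genes of the region, chosen after their values were seen, and grey for neighbours; colour gives acetate and symbol gives time. The 5 genes have a median log2 change between -2.07 and -3.50, and values of mRNA_7239 rest on 1 to 7 counts per low-nitrogen group, so its fitted changes are imprecise.

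The third question was how each culture changed from 48 to 88 h. In low nitrogen without acetate mRNA_1652 (protein 10020, scaffold 11, 812237 to 813355) rose from 2.97 ± 0.900 to 127 ± 62.3 CPM and mRNA_1303 (protein 9671, scaffold 10, 870769 to 871645) from 2.73 ± 0.618 to 103 ± 79.3 CPM. The log2 fold change of mRNA_1303 was 5.23, and 4.53 without replicate 2 at 88 h. There mRNA_7617 (protein 15985, scaffold 8, 691026 to 692859) fell from 286 ± 17.2 to 1.77 ± 0.443 CPM (log2 fold change -7.25, SE 0.49, adjusted p = 1.12e-13), and mRNA_6192 (protein 14560, scaffold 6, 219082 to 221176), which overlaps a gene on the other strand, from 23.9 ± 1.95 to 0.624 ± 0.155 CPM. In low nitrogen with acetate mRNA_6406 (protein 14774, scaffold 6, 736897 to 739297) rose from 9.13 ± 1.09 to 654 ± 79.9 CPM and mRNA_1652 from 0.816 ± 0.444 to 50.3 ± 23.1 CPM. The falls there were those of mRNA_7617, from 276 ± 49.3 to 8.52 ± 1.75 CPM, and of mRNA_5193 (protein 13561, scaffold 4, 119123 to 121882), from 14.0 ± 1.35 to 0.784 ± 0.406 CPM.

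In high nitrogen without acetate mRNA_4664 rose from 13.2 ± 1.32 to 687 ± 422 CPM and mRNA_3160 (protein 11528, scaffold 16, 454625 to 455775) from 9.64 ± 6.64 to 480 ± 251 CPM. The log2 fold change of mRNA_3160 was 5.64, and 6.35 without replicate 2 at 48 h and 5.14 without replicate 2 at 88 h. The falls were those of 2 genes of 1 strand on scaffold 3 that overlap from 1011641 to 1011730. Whether they share reads was not checked, so counts from the overlap are uncertain. The 2 genes were mRNA_4786 (1010783 to 1011730), from 33.5 ± 4.94 to 0.516 ± 0.433 CPM, and mRNA_4787 (1011641 to 1014528), from 377 ± 59.4 to 8.66 ± 3.83 CPM. The log2 fold change of mRNA_4786 was -6.03, and -7.04 without replicate 2 and -5.47 without replicate 1 at 88 h. In high nitrogen with acetate mRNA_1652 had 2 counts over the 3 libraries at 48 h and 155 ± 10.2 CPM at 88 h, a ratio of 6477 with a 95% Poisson interval of 1793 to 53485 that covers counting error only. There mRNA_1581 rose from 2.09 ± 0.172 to 970 ± 74.5 CPM (log2 fold change 8.86, SE 0.28, adjusted p = 9.71e-21), and mRNA_6255 fell from 1681 ± 258 to 3.82 ± 0.251 CPM (log2 fold change -8.79, SE 0.30, adjusted p = 5.67e-20). The next-largest fall was that of mRNA_3377 (protein 11745, scaffold 17, 531386 to 533428), from 346 ± 69.2 to 4.85 ± 0.975 CPM.

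Time changed 6121 genes in low nitrogen without acetate, 6191 with it, 5437 in high nitrogen without acetate and 5585 with it. The 2-fold changes were 1061 higher and 1287 lower, 1296 and 1161, 888 and 599, and 918 and 794, in that order. In low nitrogen 3008 genes were higher and 3113 lower without acetate, against 2205 and 3835 with library totals alone. With acetate there 3236 were higher and 2955 lower, against 2086 and 4057. In high nitrogen 2723 were higher and 2714 lower without acetate, against 3652 and 1809 with totals alone, and with acetate 2767 and 2818, against 2268 and 3482.

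The last question was whether the acetate effect itself depended on nitrogen or time, tested as interaction terms. The gene mRNA_5861 rose with acetate in low nitrogen at 88 h, while in high nitrogen it stood at 61.0 ± 26.2 CPM without and 15.7 ± 0.633 CPM with acetate; the difference of the log2 changes was 8.63 (SE 0.41, adjusted p = 8.34e-16). The gene mRNA_1581, lowered by acetate in low nitrogen at 88 h, stood in high nitrogen at 750 ± 87.0 CPM without and 970 ± 74.5 CPM with acetate (difference -7.60, SE 0.30, adjusted p = 2.50e-17). The adjacent genes mRNA_1168 (protein 9536, scaffold 10, 560830 to 563177, minus strand) and mRNA_1169 (plus strand) stood at 1189 ± 373 and 1111 ± 366 CPM in low nitrogen without acetate at 88 h. In the other low-nitrogen groups they stood between 21.1 and 41.1 CPM, and the acetate effect of mRNA_1169 fell by 4.93 log2 units from 48 to 88 h (SE 0.25, adjusted p = 2.87e-15).

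The acetate effect differed between nitrogen media for 4719 genes at 48 h, 4656 at 64 h and 5236 at 88 h. Positive differences, a higher acetate change in low nitrogen, numbered 2355 and negative ones 2364 at 48 h, against 3281 and 1538 with library totals alone. At 64 h they numbered 2656 and 2000, and at 88 h 2729 and 2507, against 4535 and 1263 with totals alone. The acetate effect differed between 48 and 88 h for 3529 genes in low nitrogen, 2000 upward and 1529 downward, against 1579 and 1943 with totals alone. In high nitrogen it differed for 5640 genes, 2811 upward and 2829 downward, against 1789 and 3897.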

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

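The tests of scaling for the raised genes, of thinned counts, of libraries that stand apart, of spread by group and of chance placement of neighbours were chosen only after the results were seen, as were the gene sets and runs they concern.

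The acetate effect differed between nitrogen media, by the interaction test, for 4719 genes at 48 h, 4656 at 64 h and 5236 at 88 h. It differed between 48 and 88 h for 3529 genes in low and 5640 in high nitrogen. At 48 h the largest differences, low minus high nitrogen in log2, were those of mRNA_3853 (5.96), mRNA_6587 (5.84), mRNA_7939 (-8.18) and mRNA_8094 (-7.38, overlapping a gene on the other strand). At 64 h they were those of mRNA_5861 (6.79), mRNA_4664 (5.57), mRNA_7939 (-10.44) and mRNA_4318 (-5.37). The values of mRNA_7939 rest on 7 counts at 48 h and 4 at 64 h in low nitrogen with acetate, so their size is imprecise. At 88 h they were those of mRNA_5861 (8.63), mRNA_4664 (6.34), mRNA_1581 (-7.60) and mRNA_6044 (-5.92). Between 48 and 88 h, the acetate effect in low nitrogen differed most for mRNA_4051 (5.80), mRNA_4787 (5.30, overlapping a neighbour on its strand), mRNA_1169 (-4.93) and mRNA_1168 (-4.72). In high nitrogen it differed most for mRNA_4787 (9.62), mRNA_1581 (9.25), mRNA_6255 (-9.78) and mRNA_7148 (-8.23).

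For each interaction, 2 of the 100 splits drawn gave as many genes, the real one and the one with acetate labels exchanged in 1 of the 2 strata. With that exchange the term is the sum of both acetate effects and not their difference, and it called 5662 genes at 48 h, 5148 at 64 h, 6025 at 88 h, 4694 between times in low nitrogen and 6406 in high nitrogen. The highest of the remaining splits gave 4518, 4336, 5113, 2541 and 4470 genes, in that order. At 0.02 of splits, the real count thus lay above every split drawn that mixed acetate and control libraries in at least 1 stratum. The splits that kept the acetate groups whole in 1 stratum gave between 1019 and 5113 genes, since the term then holds the acetate effect of that stratum, and those that kept neither gave at most 5. No split keeps both acetate effects without their difference, so the splits do not decide whether the effects differ, which rests on the interaction term alone. The draws were first made at 60 per interaction and looked at, and then raised to 100 with the same seeds.

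For each of the 16 pairwise comparisons, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Real count and highest other split for acetate in low nitrogen were 4249 and 0, 3481 and 1, and 3948 and 35 at 48, 64 and 88 h. In high nitrogen they were 5729 and 533, 5559 and 94, and 6287 and 55. For nitrogen without acetate they were 4907 and 0, 6135 and 151, and 6440 and 207, and with acetate 5838 and 199, 6315 and 1, and 6428 and 0. For time they were 6121 and 0 in low nitrogen without acetate and 6191 and 0 with it. In high nitrogen they were 5437 and 586 without and 5585 and 81 with acetate.

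Among genes raised by acetate at 48 h, the acetate change at 88 h was smaller in high than in low nitrogen. The difference was 0.81 log2 units from the fitted fold changes and 0.76 from library scores. The pattern was first worded for all acetate-responsive genes and narrowed to raised ones after the set values were seen, and the lowered genes differed by -0.28 from library scores and -0.23 from fitted fold changes, which turned to 0.23 with totals alone and was -0.11 without replicate 1 of high nitrogen with acetate. The values argue against scaling (0.82 with RLE, 1.26 with totals alone), against unequal depth (0.89 after thinning) and against a single mislabelled library (lowest of 12 left-out values 0.75). With the 3 libraries that stand apart left out it was 0.82, and 0.80 with 1 more, in low nitrogen, left out too. At 88 h the library scores of the set differed between media mostly without acetate (2.88 to 3.04 in low, 3.81 to 3.92 in high nitrogen). With acetate they lay close (3.98 to 4.15 and 4.17 to 4.21). At 48 h, where the genes were picked, scores with acetate had been 4.94 to 5.22 in low and 5.78 to 6.08 in high nitrogen. Without acetate they had been 3.15 to 3.19 and 3.40 to 3.46. Nitrogen supply is what the design names, and a dependence of the acetate response on it may underlie the difference, as a hypothesis found on these data.

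Acetate changed fewer genes in low than in high nitrogen, with ratios of calls of 0.742, 0.626 and 0.628 at 48, 64 and 88 h. After thinning the highest ratio was 0.665, and under other scalings 0.749, which argues against depth and scaling. With the 3 libraries of high nitrogen that stand apart left out, the ratios were 0.828, 0.814 and 0.757, and 0.835, 0.753 and 0.757 with 1 more, in low nitrogen, left out too, so the size of the difference depends on such libraries. The ratio of standard errors had been set to test spread, but a shared fit makes these near equal by its construction, so it decides nothing. Spread estimated by group and pooled over the 2 groups compared was smaller in low nitrogen at each time (0.0596 against 0.145, 0.114 against 0.139, 0.0825 against 0.134). Without the 3 libraries it stayed smaller there at 48 h (0.0596 against 0.107) but was larger at 64 and 88 h (0.114 against 0.0795, 0.0825 against 0.0664). The median absolute log2 change of all genes was smaller in low nitrogen at each time (0.310, 0.272 and 0.300 against 0.488, 0.441 and 0.595). Larger spread in low nitrogen would enlarge it there, so these values argue against such spread as the cause. Leaving out libraries that stand apart lowered no count of calls below 0.985 times the reported one. The higher ratios without the 3 libraries thus came mostly from more calls in low nitrogen, where none was left out. Calls in high nitrogen hardly fell when its spread did. Leaving libraries out also changes the shared fit, so the effect of that spread with all libraries kept was not tested by itself. That effect stays open beside nitrogen supply itself.

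Neighbouring genes changed together with nitrogen in runs. Genes in such runs overlapped a neighbour 1.20 times as often as all tested genes (95% binomial interval 1.05 to 1.37). The interval takes genes as independent, which adjacent genes are not, so it is too narrow. The ratio lies below the bound of 1.5 times set against reads shared by annotated overlap. Reads that span abutting genes, such as those with a gap of 0 bp on scaffold 7, were not counted, so shared reads of that kind stay open. Against chance placement, the highest p over the 12 tests of nitrogen was 5e-04, where 1e-04 is the smallest that 10000 shuffles can give. Runs also passed this test in 7 of 12 acetate and 6 of 8 time tests (adjusted p below 0.05), so they are not particular to nitrogen. Whether neighbours share regulation was not tested, and it may be so only as a hypothesis.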

How the results depend on the processing

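Thinning and leaving out the libraries that stand apart were chosen only after the data were seen, as were the gene sets, correlations and runs below. Counts of called genes stayed within 1.5 times under each alternative, with ratios to the reported count of 0.780 to 1.36, or 0.787 to 1.03 with 1 library left out and 0.985 to 1.28 with the 3 or 4 libraries that stand apart left out together, and named genes kept direction and call under each alternative that gave a value. With library totals alone, the mean log2 change with acetate of genes raised at 48h, high nitrogen, 64h, was 1.27, and the mean log2 change with acetate of genes raised at 48h, high nitrogen, 88h, was -0.15 (reversed). The mean log2 change with acetate of genes lowered at 48h, low nitrogen, 64h, was then -0.63. The mean log2 change with acetate of genes lowered at 48h, high nitrogen, 64h, was -0.81, and the mean log2 change with acetate of genes lowered at 48h, high nitrogen, 88h, was -0.34 (reversed). Totals alone differ from TMM by their construction, while the cause of the difference in composition was not tested. With 1 library left out, the mean of raised genes in high nitrogen at 88 h ranged from 0.23 (without replicate 2 with acetate) to 0.34 (without replicate 1 without acetate), and that of lowered genes from 0.01 (without replicate 1 with acetate) to 0.17 (without replicate 2 without acetate). Among runs, the number of genes in runs of neighbours, nitrogen effect, no acetate, 64h, moved from 115 to 281 with library totals alone. The number of genes in runs of neighbours, nitrogen effect, no acetate, 88h, then moved from 243 to 605, and the number of genes in runs of neighbours, nitrogen effect, acetate, 88h, moved from 237 to 138 with the stricter filter. The correlation of nitrogen effects, without and with acetate, 48h, was 0.592 with the stricter filter, and the correlation of acetate effects, low and high nitrogen, 64h, was 0.278 with none, on fewer and more genes. RLE and DESeq2 moved the median of all genes by at most 0.037 and the share of higher calls by at most 3.15 points. Adding the replicate block changed counts of calls by ratios of 0.998 to 1.008. In 0 of 66 pairs of groups did every same-numbered pair correlate above 0.1, 16 of 36 libraries were closest to their own number, and the mean r was 0.009 for same and -0.004 for different numbers. The check did not pair the samples, so numbers were not taken as pairing, and whether they mark a colony stays open. Since it asked for every same-numbered pair above 0.1, it cannot exclude flasks shared between times. In high nitrogen without acetate replicate 2 stood apart at both 64 and 88 h. Between these times r was 0.351 for replicate 2, 0.218 for replicate 1 and 0.045 for replicate 3. Gene set alternatives were not run, since the lists had no members. Depth limits levels below 0.410 CPM in the shallowest library.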

Other observations

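The tests below were written before their values were seen, but correlations of acetate effects with the change from 48 to 88 h had been looked at, so both are hypotheses from these data. One hypothesis is that cultures with acetate lie at an earlier point of the time course seen without acetate, which could give an acetate effect at 88 h opposite to the change from 48 to 64 h without acetate. In low nitrogen, Pearson's r across 8314 genes between these, from separate libraries, was -0.285 (SD 0.031 over single replicates). It lies between the bounds set beforehand, so the hypothesis stays open there. In high nitrogen r was -0.022 (SD 0.153) and Spearman's rho 0.053. There r lay past the bound set beforehand against the hypothesis. Its distance to that bound was smaller than its SD, a margin not in the bound as set, so the hypothesis is left open there as well.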
